A study of Mus musculus with 9 samples.

How the data were processed

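ATAC-seq libraries were made from HPC7 cells carrying an empty MIG retroviral vector (EV), a vector for wildtype Snai1 or a vector for the mutant named mut5Snai1, with 3 libraries in each of 3 groups, 9 in all, per the labels. Per the submitters' processing notes, fastp, Bowtie2, Picard and DiffBind were used, with the mm10 build; versions, the peak caller, any shift of reads for the Tn5 cut, the rule for counting reads in windows, the scaling and the DiffBind settings are not given in the sources used here. Reads per library are likewise not given.

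The file analysed was the authors' table of their comparison of EV with Snai1 over promoter windows. It gave, per the file headers, the authors' log2 concentration (DiffBind's term for the normalized read density of a region) over both groups, that of each group, the log2 fold, the p-value and the FDR. The concentrations are the authors' group values with no value per library, and no standard deviation or n can be attached to them. The deposited log2 fold was EV minus Snai1, equal to the difference of the group values within 0.01; its sign was turned, so that a positive change is higher in Snai1. The authors' FDR equalled a Benjamini-Hochberg adjustment of the deposited p-value over the rows of the table within 0.00136. Of 10274 rows, 3 were exact repeats and were dropped, which left 10271 windows. The number of columns of values per sample was 0, so neither a count model nor any test across libraries was run, and the authors' p and FDR (threshold 0.05) are reported as they stand. The mutant and its comparisons, and a search for the Snai1 binding motif, which needs a genome sequence, were not analysed here.

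The table names no genes. Its 5251 windows of 2001 bp ran from 1000 bp before to 1000 bp after a gene start on the plus strand. Its 5020 windows of 1101 bp ran from 1000 bp before to 100 bp after a gene start on the minus strand. This was found by matching window positions to RefSeq gene boundaries (GRCm38.p6, the same coordinates as mm10). Under this rule 4210 windows matched a 5' boundary exactly, against 5 under the opposite one. The shorter windows saw less sequence downstream of the start and had a lower median log2 concentration (10.58 against 11.02). A window was given the gene whose 5' boundary lay within 1000 bp of its start position (8572 protein-coding, 404 other), otherwise the gene that spans it (1234), and 61 had none. A window inside a gene may belong to another promoter of that gene or to a non-coding transcript. In all, 10149 genes had a window. For genes with several windows, the lists used the window with the highest mean accessibility and the named genes the one with the smallest p.

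For precision, a standard error was worked back from each change and its p-value (the change divided by the normal deviate of p) and is called the implied SE; windows changed by less than 0.1 log2 or with p listed at 0 took the median of their accessibility bin (20 bins). Its median was 0.18 in the lowest decile of accessibility, 0.11 in the second and between 0.08 and 0.09 in the others, so small changes were hardest to call in the lowest decile. Re-tests subtracted the median of all windows, or of the window's stretch of chromosome, from the change, divided by the implied SE and adjusted by Benjamini-Hochberg. Stretches came from an optimal partition of the changes along each chromosome, with windows of log2 concentration of at least 9, at least 15 windows per stretch, changes limited to 0.75 log2 from the centre and a penalty of 4 times the variance times the log of the number of windows. A stretch of at least 15 windows counted as shifted where its median lay at least 0.2 log2 from that of all windows; chromosome Y, with 3 windows, was a single stretch below that minimum and was not counted. Neighbouring shifted stretches of the same sign were joined into regions. The partition, the implied SE and both re-tests were designed after the data were examined.

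Before the data were examined, 13 lists of genes and a rule for ribosomal proteins (14 lists) were fixed: epithelial, mesenchymal, stem and progenitor regulators, granulocyte and monocyte, erythroid and megakaryocyte, lymphoid, mast cell and basophil, fibroblast, the Lsd1, CoREST and HDAC complex, adhesion and migration, cell cycle, p53 and apoptosis, interferon response and ribosomal proteins. Each list's median change was set against 10000 random lists of the same size matched on accessibility decile (genes drawn anew within each decile; called a permutation test here; two-sided; smallest p it can give 0.0001), its share of called genes against other genes by two-sided Fisher's exact test, and both were adjusted over the 14 lists. The rule for named genes, also fixed then, took the 10 largest increases and the 10 largest decreases among called windows, leaving out predicted genes, up to 4 called genes with the smallest FDR from each list (with none called, the 2 with the smallest p), and Snai1, Cdh1 and Kdm1a; other members are given as values. Some genes that the rule takes are not reported here, although the counts include them. Called windows per chromosome were compared with all others by two-sided Fisher's exact test.

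The steps were tested on simulated changes with the real positions, errors and number of windows (10271) of the Snai1 and EV comparison. The partition recovered 99 of 100 planted blocks of 40 windows shifted by 0.3 log2 and called 0 elsewhere. The list test gave p under 0.05 for 2% of unshifted lists of 30 genes and for 99% of lists shifted by 0.15. That check used changes with stretch medians subtracted, unlike the main list test. Several fixed lists had far fewer than 30 genes with a window, so the check does not give the power for them. The re-test recovered 41% of 200 windows changed by 0.3 log2 and 93.5% of 200 changed by 0.6, with 2.4% and 5.6% of its calls unchanged windows. Its noise was drawn from the implied SE around the known stretch medians, and the re-test used both. It therefore could not check whether the implied SE or the stretch medians are right. Alternatives covered the FDR threshold, a minimum fold, accessibility, one window per gene, the centre of the changes, the shifted regions, window width, the choice of window in the lists and the matching of random lists. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used.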

Results

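Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in HPC7 cells, a mouse hematopoietic progenitor line that grows in stem cell factor. The cells carried a retroviral vector: 3 libraries came from cells with the empty vector (EV), 3 from cells with a vector for FLAG-tagged wildtype Snai1, and 3 from cells with a Snai1 mutant. Snai1 is a zinc finger repressor best known for silencing epithelial genes during epithelial-mesenchymal transition. The authors' deposited table compared Snai1 with EV at 10271 promoter windows and gave 1 mean per group, so all changes below are Snai1 minus EV of those means, with the authors' p and FDR. The table holds no value per library, and the number of reads behind each library is not given in the sources used here. The labels do not say that the 3 libraries of a group came from separate transductions, so the p-values measure the spread between libraries, which may be technical. The mutant was not analysed here.

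The comparison of Snai1 with EV asked which promoters opened or closed when the progenitors carried Snai1. In the authors' deposited table, 3075 of the 10271 windows (29.9%) passed FDR 0.05, 2015 of them higher and 1060 lower in Snai1. Most changes were small: the median was 0.26 on the log2 scale (1.2-fold) among the higher windows and -0.41 (1.33-fold) among the lower ones. The strongest changes were at single promoter windows. Those of the purinergic receptor gene P2ry1 and the insulin signalling adaptor gene Irs2, and a window inside the Wnt feedback gene Axin2, opened. Those of the tight junction gene Ocln, the phosphodiesterase gene Pde3b and the zinc finger gene Zfp53 closed. Stretches of chromosomes 1, 4, 5, 12 and 16 were shifted as blocks, and 50.8% of all lower windows lay in them.

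**Figure D1:**
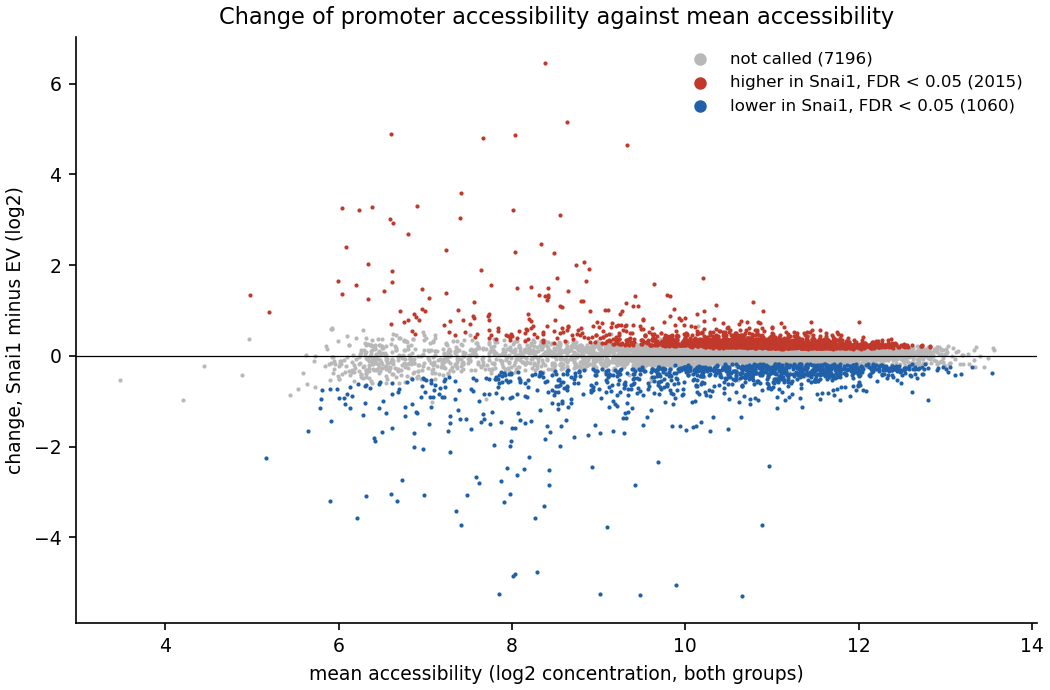
Each point is a promoter window of the authors' deposited table, with the mean accessibility of both groups (log2 concentration) on the x axis and the change, Snai1 minus EV (log2), on the y axis; red and blue mark windows at FDR under 0.05. The 2015 higher and 1060 lower windows lie mostly near 0 at high accessibility, and changes of several log2 units lie at windows of lower mean accessibility.

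The largest increases in the authors' deposited table were at windows of low accessibility in EV, and in Snai1 they still lay below the median window (log2 concentration 10.81). The window at P2ry1 (mm10, chromosome 3, 61001785 to 61003785, at the 5' boundary of the gene), which encodes an ADP receptor of platelets, rose from a log2 concentration of 4.45 in EV to 9.60 in Snai1 (change 5.15, implied SE 0.37, FDR 7.39e-41). Irs2 (chromosome 8, 11008330 to 11009430), an adaptor of the insulin receptor, rose by 4.81 (implied SE 0.27, FDR 4.45e-66), and Mtmr10, of the myotubularin family, by 4.66 (implied SE 0.34, FDR 4.15e-40) in the authors' deposited table. Rnls, a renalase gene annotated in RefSeq as a transcribed pseudogene, rose by 4.90, and Epdr1 by 3.31, both at a window on the annotated 5' boundary. Several of the strongest increases lay inside genes rather than at their annotated start. Axin2, which encodes an inhibitor induced by Wnt signalling, rose by 4.87 (implied SE 0.23, FDR 1.34e-92) in the authors' deposited table, at a window 2521 bp inside the gene. Windows inside Sec24d (3.59), the transcription factor gene Tfap2a (3.28) and the RNA-binding protein gene Rbms1 (3.25) were also among the 10 largest increases in the authors' deposited table.

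The largest decreases in the authors' deposited table all lay at annotated 5' ends, and 8 of the 10 were below the median window (10.81) in EV as well, the exceptions being Zfp53 and Btg3. Zfp53 (chromosome 17, 21487988 to 21489988), a zinc finger gene, fell from 11.62 to 6.32 (change -5.30, p listed at 0). Another pair of zinc finger genes, Zfp2 (-4.86) and Zfp820 (-4.77), were also among the 10 largest decreases in the authors' deposited table. Tdrkh, a tudor domain gene of the germline piRNA pathway, changed by -5.28 (implied SE 0.16, FDR 1.05e-231). Pde3b, a phosphodiesterase that breaks down cyclic AMP, changed by -5.26 (implied SE 0.18, FDR 2.05e-175), and Pag1, a membrane adaptor that holds Src family kinases in check, by -5.26 with a wider error (implied SE 0.59, FDR 1.83e-17). Ocln (chromosome 13, 100552398 to 100553498), which encodes the tight junction protein occludin, fell from 8.99 to 4.18 (change -4.81, implied SE 0.23, FDR 2.19e-95) in the authors' deposited table. The antiproliferative gene Btg3 (-5.06) lay in a shifted stretch of chromosome 16, far below that stretch's median of -0.39. The potassium channel gene Kcnk5 (-3.78) and the X-linked lymphocyte-regulated gene Xlr4a (-3.74) closed the list; Xlr4a has near-identical copies, so its reads are uncertain. Of the 66 windows changed by at least 2 log2 units in the authors' deposited table, 25 were higher and 41 lower in Snai1, and all 25 and 35 of the 41 lay outside the shifted stretches.

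**Figure D2:**
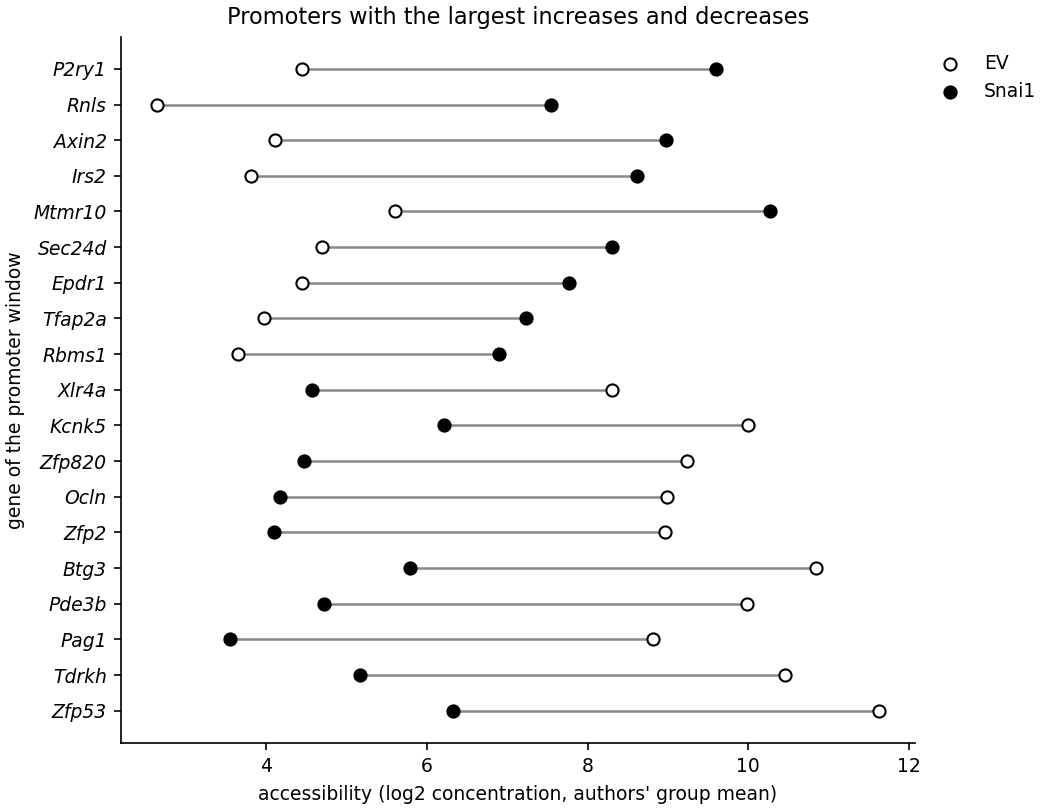
Accessibility (log2 concentration, the authors' group means) of 9 of the 10 promoters with the largest increases and the 10 with the largest decreases, in EV (open circles) and Snai1 (filled circles); no error bars are drawn because the table gives no value per library. P2ry1 runs from 4.45 to 9.60 and Zfp53 from 11.62 to 6.32.

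The window at the endogenous Snai1 gene was itself lower in the Snai1 cells. In the authors' deposited table it fell from 9.81 to 8.43 (chromosome 2, 167537227 to 167539227; change -1.38, implied SE 0.13, FDR 4.17e-26). Kdm1a, which encodes the histone demethylase Lsd1 that Snai1 recruits, had a change of -0.03 (implied SE 0.09, FDR 0.81). No window was assigned to Cdh1, the E-cadherin gene.

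Epithelial genes were sparsely represented. Only 8 of 35 had a window in the authors' deposited table: 1 rose, Ocln and F11r (-0.51) fell, and 5 did not pass, among them Ctnnb1 (-0.05) and Jup (0.00). With stretch medians subtracted and the changes tested again (called stretch-centred from here on), 0 were higher and 3 lower. F11r, another junction gene, lay in the shifted stretch of chromosome 1. Of 16 mesenchymal genes with a window, 5 rose, 3 fell and 8 did not pass; stretch-centred, 2 were higher and 4 lower. The calcium-binding protein gene S100a4 rose by 0.66 (FDR 9.33e-12) and a window inside the integrin gene Itgav by 0.35 (FDR 7.73e-06) in the authors' deposited table. The matrix protease gene Mmp14 changed by -0.90 (FDR 6.59e-05), and Vim, which encodes vimentin, had a value of -0.10 (FDR 0.31). Neither list stood apart in the permutation test against random lists matched on accessibility: the median was -0.03 for epithelial genes (adjusted p = 0.678) and 0.06 for mesenchymal genes (adjusted p = 0.876). The random-list ranges were wide, -0.09 to 0.20 and -0.055 to 0.165, so a moderate shift of lists this short could be missed.

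Regulators of blood stem cells and progenitors moved in both directions. Of 22 with a window, 6 rose and 5 fell in the authors' deposited table; adjusted over the list alone the counts were again 6 and 5, but stretch-centred 1 was higher and 3 were lower. A window deep inside Mecom, a stem cell transcription factor gene, fell by 1.51 (FDR 1.06e-17), and Gfi1, a repressor related to Snai1 by its SNAG domain, fell by 0.80 (FDR 3.16e-07). Myc rose by 0.37 (FDR 1.40e-06) in the authors' deposited table. Runx1 changed by -0.61 (FDR 1.66e-06), but lay in a stretch of chromosome 16 whose median was -0.69; set against that median its change was 0.08. Kit, the receptor for stem cell factor, had a value of -0.08 (FDR 0.35).

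Among granulocyte and monocyte genes, 4 of 20 rose and 3 fell in the authors' deposited table, and 4 were higher and 4 lower when stretch-centred. Cebpb, a transcription factor of myeloid differentiation, rose by 1.90 (implied SE 0.19, FDR 9.82e-21), Cd14 by 1.03 (FDR 9.5e-05) and Cebpe by 0.50 (FDR 3.39e-05). A window inside Csf3r, the receptor for granulocyte colony-stimulating factor, fell by 1.69 (implied SE 0.15, FDR 3.01e-27), and Ltf, the gene of the granule protein lactoferrin, fell by 0.99 (FDR 7.48e-11). Spi1, which encodes the myeloid master regulator PU.1, had a value of 0.02 (FDR 0.87) in the authors' deposited table. Of 17 erythroid and megakaryocyte genes, 3 rose, among them Itga2b (0.30) and Ppbp (0.59), and 2 fell, among them Tfrc (-0.43), which lay in a shifted stretch of chromosome 16; stretch-centred, 2 were higher and 0 lower. Of 8 lymphoid genes, Gata3 rose (0.38) and Notch1 (-2.67, FDR 1.24e-36) and Bcl11a (-0.52) fell in the authors' deposited table, with the same counts of 1 and 2 when stretch-centred. The Gata3 and Bcl11a windows lay inside the gene, 9353 and 1492 bp from its annotated 5' boundary. Of 9 mast cell and basophil genes, Mitf (0.38), Gata2 (0.25) and the granzyme gene Gzmb (1.21) rose and Cd200r3 (-0.59) fell, against 2 higher and 0 lower when stretch-centred. The Gata2 window lay inside the gene. Of 15 fibroblast genes, kept as markers of another cell type, only 2 had a window. Fap rose (0.38, at a window inside the gene) and Pdgfrb had a value of 0.08 (FDR 0.67). Neither was called when stretch-centred.

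The genes of the complexes that Snai1 works with changed little. In the authors' deposited table, 13 of 16 genes of the Lsd1, CoREST and HDAC list did not pass, among them Hdac1 (-0.05) and Hdac2 (0.08). Ezh2, the Polycomb methyltransferase gene, rose by 0.21. Rcor1 (-0.42) and Rcor3 (-0.22) fell, both inside shifted stretches, of chromosomes 12 and 1; adjusted over the list alone, 1 gene rose and 1 fell, and 0 of the 16 were called when stretch-centred. Adhesion and migration genes were split, with 6 of 29 higher and 6 lower in the authors' deposited table, and 2 higher and 4 lower when stretch-centred. Cd47, the signal that inhibits phagocytosis, changed by -0.95 in a shifted stretch of chromosome 16, Icam2 by -0.78 (FDR 1.49e-10) and the integrin gene Itga2 by -0.51. The Cd47 and Icam2 windows lay inside the gene. Pecam1 rose by 0.50 (FDR 1.14e-04).

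The cell cycle and the p53 and apoptosis lists had medians on opposite sides of their random-list ranges, but neither passed its adjusted test. Of 35 cell cycle genes in the authors' deposited table, 13 rose and 1, the inhibitor gene Cdkn1a (-1.04), fell; the median was 0.15 against a random-list range of 0.03 to 0.14 (p = 0.0576, adjusted p = 0.403). Stretch-centred, 3 were higher and 1 lower, and the median of 0.04 lay inside the random-list range of -0.05 to 0.05 (permutation test, p = 0.145). Cyclin genes Ccne2 (0.75) and Ccnd2 (0.48) and the replication helicase genes Mcm4 (0.40) and Mcm5 (0.31) had the smallest FDR values of the list. Ccne2 and Mcm4 lay in shifted stretches of chromosomes 4 and 16, and the Ccnd2 window lay inside the gene. Of 25 p53 and apoptosis genes, 3 rose and 4 fell; stretch-centred, 0 were higher and 3 lower. Gadd45a, a growth arrest gene, fell by 3.10 (implied SE 0.30, FDR 1.46e-22) in the authors' deposited table. Mdm4, which encodes a p53 inhibitor, changed by -0.30 in the shifted stretch of chromosome 1, Trp53inp1 by 0.64 in that of chromosome 4, and the cell death gene Bcl2l11 by 0.29. The Mdm4 and Bcl2l11 windows lay inside the gene. The p53 and apoptosis median of -0.03 lay below the random-list range of 0.00 to 0.15 (permutation test, p = 0.0089, adjusted p = 0.125).

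Interferon-response genes moved both ways, 4 of 16 higher and 2 lower in the authors' deposited table, and 1 higher and 2 lower when stretch-centred. Ifit2 (0.46, FDR 1.07e-08) and Usp18 (0.33, FDR 3.53e-04) rose, whereas Rsad2 fell by 1.40 (FDR 9.79e-15) and Mx2, annotated as a transcribed pseudogene and in a shifted stretch of chromosome 16, fell by 1.34 (FDR 2.36e-57). Of 73 ribosomal protein genes, 14 rose, among them Rps13 (0.31), Rpl37a (0.32) and Rps20 (0.57, in a shifted stretch of chromosome 4), and 2 fell, Rpl35a (-0.52) and Rpl24 (-0.36), both on chromosome 16. Stretch-centred, 2 ribosomal protein genes were higher and 1 lower. The list median of 0.10 lay inside the random-list range of 0.05 to 0.13. In all, 0 of the 14 lists stood apart from matched random lists after Benjamini-Hochberg adjustment, with 1 list (p53 and apoptosis) at an unadjusted p under 0.05, and 0 held an unusual share of changed genes by two-sided Fisher's exact test (0 unadjusted either; lowest p 0.0589, stem and progenitor regulators). Stretch-centred, granulocyte and monocyte genes did by Fisher's exact test: 4 were higher and 4 lower of 20 (40% against 12.4% of other genes, odds ratio 4.70, p 0.00181, adjusted p 0.0254). Their median of -0.08 lay inside the random-list range of -0.15 to 0.06. Among these calls, Fcgr3 (0.08, FDR 0.57) and Cd68 (-0.23, FDR 0.10) did not pass in the authors' deposited table. Fisher's exact test was not matched on accessibility.

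**Figure D3:**
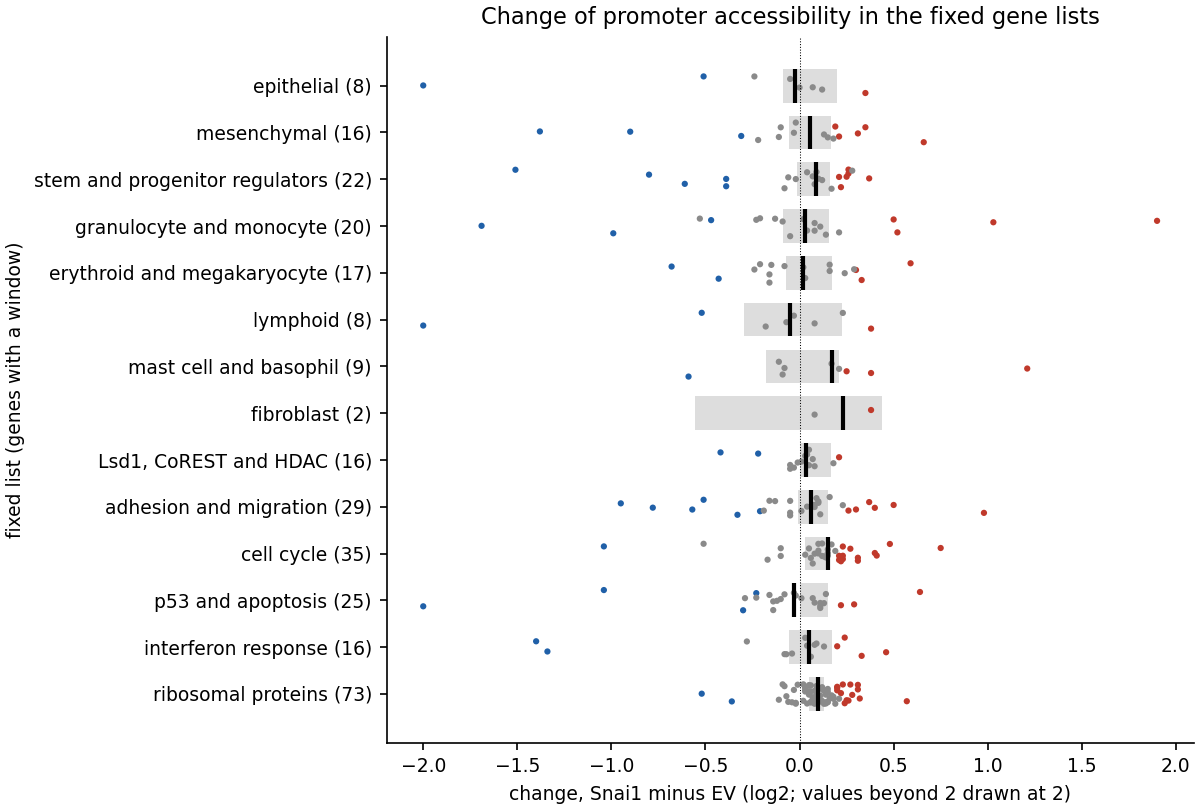
Change of promoter accessibility (Snai1 minus EV, log2) for each gene of the 14 fixed lists; points are genes (red higher, blue lower at FDR under 0.05, grey not passing), black bars are list medians and grey boxes hold the middle 95% of 10000 random lists matched on accessibility. The p53 and apoptosis median of -0.03 lies below its box and the cell cycle median of 0.15 just above its box.

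Changed promoters were unevenly spread over the chromosomes. On chromosome 16, 82.4% of 335 windows passed in the authors' deposited table and 66.9% were lower in Snai1 (median change -0.35; two-sided Fisher's exact test against all other windows, odds ratio 11.9, adjusted p 8.31e-90). On chromosome 1, 43.8% passed and 37.5% were lower, and on chromosome 12, 41.5% passed and 23.9% were lower. Chromosome 5 had the lowest share, 17.5%. The test passed for 13 of 21 chromosomes, with a higher share of called windows on chromosomes 1, 6, 12 and 16 and a lower share on the others. It passed for 0 (also 0 unadjusted) once each window was set against the median of its own stretch. Fisher's exact test treats windows as independent although neighbours are not, so its p-values overstate the evidence.

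Dividing each chromosome into stretches of like change found 7 shifted regions that held 891 windows (8.67%) and 653 of the called ones. In the authors' deposited table, 73.3% of windows inside them passed, against 25.8% outside. Chromosome 16 was lower from 16.9 to 98.1 Mb over 268 windows (median -0.40, 98.1% of windows on that side of the median of all windows). Within it, the stretch from 43.9 to 52.0 Mb, which holds Cd47 and Cd200r3, had a median of -0.88, and that from 92.1 to 98.1 Mb, which holds Runx1 and Mx2, -0.69. The first part of chromosome 16, from 3.74 to 16.4 Mb, which holds Mcm4, was higher (67 windows, median 0.32). Chromosome 1 was lower from 92.5 to 195.1 Mb (345 windows, median -0.24), and chromosome 12 from 91.6 to 118.3 Mb (104 windows, median -0.33), a stretch with Rcor1. Chromosome 4 was higher from 3.57 to 35.2 Mb (62 windows, median 0.52), where Ccne2, Trp53inp1 and Rps20 lie, and lower from 58.9 to 62.5 Mb (21 windows, median -0.35). A short stretch of chromosome 5, from 115.6 to 120.6 Mb, was lower (24 windows, median -0.20). The 2 window widths of the table gave medians of the same sign in every region.

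**Figure D4:**
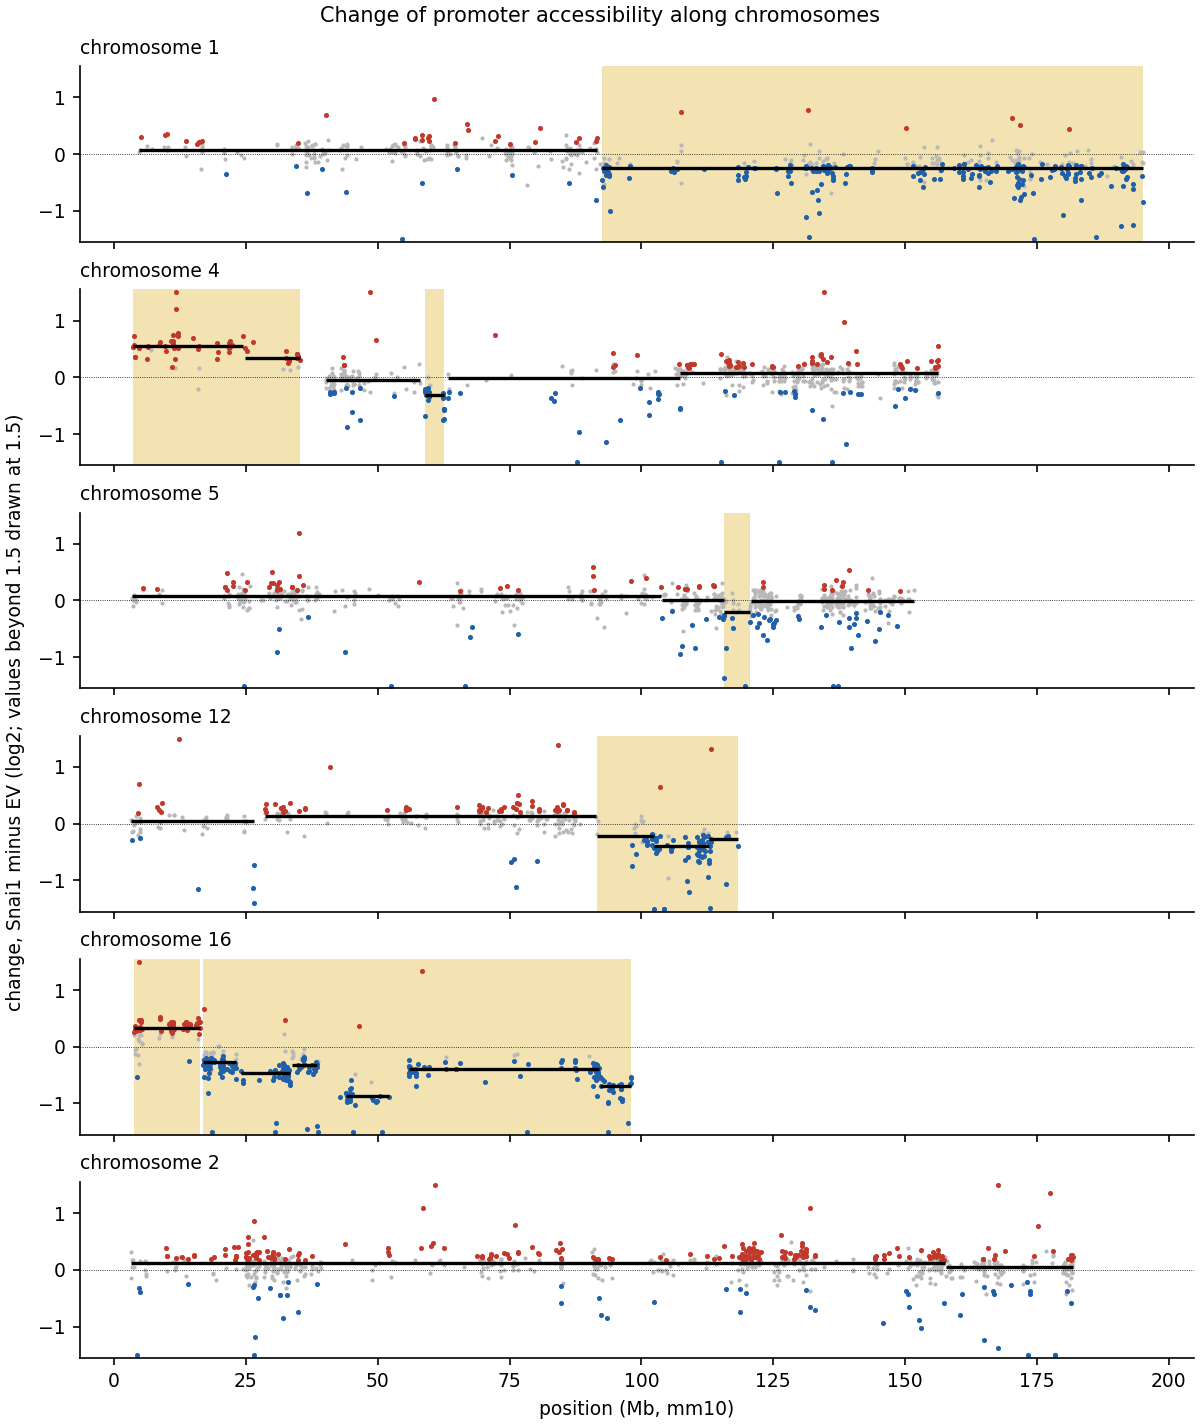
Change of each promoter window (Snai1 minus EV, log2) against its position (Mb, mm10) on chromosomes 1, 4, 5, 12 and 16, and on chromosome 2, which has no shifted region; red and blue points pass FDR 0.05, black lines are stretch medians and shading marks the 7 shifted regions. Chromosome 16 steps from a stretch median of 0.33 to -0.275 near 16.9 Mb, and chromosome 1 to -0.24 at 92.5 Mb.

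The balance of opening and closing depended on the size of change and on the centre from which it was measured. Of the 3075 called windows in the authors' deposited table, 65.5% were higher in Snai1 (two-sided exact binomial test, p 2.10e-67, which treats windows as independent although neighbours are not). The median change of all windows was 0.08, and after subtracting it and testing again, 34.5% of 2156 called windows were higher (743 higher, 1413 lower). Of these 2156, 1803 were among the authors' calls in the same direction. Subtracting the median of each stretch and testing again called 1284 windows, 456 higher and 828 lower (35.5% higher). Of these 1284, 991 were among the authors' calls in the same direction. Among windows changed by at least 1.5-fold the split was 154 higher and 322 lower (32.4% higher), so the many small increases, not the large changes, made up the majority. Part of the large decreases lay in shifted regions. At 1 log2 or more, 72 were higher and 136 lower in all, against 67 and 105 outside those regions. Of called windows of any size, 1900 were higher and 522 lower outside the shifted regions (78.4% higher). The large decreases, such as those at Zfp53, Tdrkh, Ocln, Notch1 and Gadd45a, and the large increases, such as those at P2ry1, Irs2 and Cebpb, passed with either centre.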

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

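The re-tests with another centre, the counts without shifted regions, the split by size of change, the single window widths and the lists limited to windows within 100 bp of a 5' boundary were chosen after seeing the data; the other alternatives were planned. The count of 3075 changed windows became 1947 at FDR 0.01, 476 with a change of at least 1.5-fold, 208 with at least 1 log2, 1572 among windows above the median accessibility and 1284 after subtracting stretch medians; all but the last follow from fewer windows or a stricter limit. It stayed within 1.5 times of 3075 at FDR 0.1 (3871), counting genes (3041), outside the shifted regions (2422) and after subtracting the median of all windows (2156). The share of higher windows, 65.5%, turned below 50% at 1.5-fold (32.4%) and at 1 log2 (34.6%). It also did so after subtracting the median of all windows (34.5%) and stretch medians (35.5%), both with a new test. The planned centring took the sign of the change minus the median of all windows, among the authors' calls. It gave the same 2015 higher and 1060 lower (65.5%), because no called increase was smaller than that median of 0.08. That setting therefore could not show whether the share depends on the centre. The share was 59.2% at FDR 0.01, 68.5% at FDR 0.1, 68.7% in the wider windows alone and 61.9% in the narrower. The uneven spread over chromosomes (13 with an adjusted p under 0.05) held for 12 on the autosomes, 13 at FDR 0.01 and 9 without the shifted regions, and for 0 after subtracting stretch medians, which removes such differences by construction. The number of lists apart from random lists was 0 in the report and under every other alternative but that without windows in shifted regions, where it was 1: the p53 and apoptosis list (median -0.02, adjusted p 0.028; over its other alternatives the adjusted p ran from 0.0658 to 0.372); the cause was not tested. The number of lists with an unusual share of changed genes by Fisher's exact test was 0, and 1 (granulocyte and monocyte, adjusted p 0.0254; 0.387 to 1 under the others) after subtracting stretch medians, the cause of which was not tested.

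Of 70 named genes, 68 kept their direction and their side of the threshold after subtracting the median of all windows, with Gata2 (0.17) and Ezh2 (0.13) no longer past the threshold. After subtracting stretch medians 51 kept both, 15 kept the direction only, and 4 reversed: Runx1 (0.08), Tfrc (0.03), Cd200r3 (0.29) and Rcor3 (0.02), none past the threshold; these 4 lie in shifted regions, whose medians account for the reversal. No paired analysis was possible because the authors' deposited table gives 1 value per group and none per library; for the same reason leaving out libraries, other splits of the libraries, other normalizations, pseudocounts and filters per library were not run. The comparisons with the mutant, their overlap with the Snai1 changes and the motif search were not run either. The depth per library is not known, and the implied SE of 0.18 in the lowest decile of accessibility limits what could be called at such windows.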

Other observations

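Apart from the test on windows left out of the partition, the test on other windows near histone genes and the S-phase test, the tests in this part were chosen after the results were seen; the genes in the next 2 paragraphs were also chosen after their values were seen.

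Several signalling genes outside the fixed lists changed strongly. Wls, which carries Wnt proteins to the cell surface, rose by 3.02 and Fgf10 by 2.69 in the authors' deposited table, while the Wnt receptor gene Fzd4 fell by 2.77, beside the increase at Axin2. Of the BMP pathway, Smad1 fell by 1.54 and its target Id3 fell by 1.59. The Notch ligand gene Jag2 fell by 1.49, like Notch1 (-2.67), although Jag2 lies in the shifted region of chromosome 12 and was 1.21 below its stretch median. Ephb4 (-1.65) and the ephrin gene Efna3 (-1.5) both fell. Among immune surface genes, Cd300a (2.27), Clec4a2 (1.57) and Ms4a3 (1.66) rose. The costimulatory genes Cd86 (-1.45) and Cd80 (-1.39, at a window inside the gene), on the shifted part of chromosome 16, stayed 1.13 and 1.07 below their stretch medians. Chromatin genes with lower windows inside the gene were Cbx7 (-3.07), Mllt3 (-2.74), Tet3 (-2.63) and Satb1 (-1.43) in the authors' deposited table. No pathway is claimed from these genes, since none was tested as a group.

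Gene families were compared by their change after subtracting stretch medians (48 families, random lists matched on accessibility). They were those sharing a symbol prefix with at least 20 genes, and 2 smaller ones added by hand outside that rule. These 2 were the genes with the symbol prefix H2- (major histocompatibility complex) and the replication-dependent histone genes. The adjusted p does not cover that choice. The H2- genes of chromosome 17 were called higher at 8 of 13 windows and lower at 0, led by H2-K1 (2.01) and H2-Ob (0.62). The H2- family did not pass against random lists (median 0.10, adjusted p 0.546), and 2 of its genes stayed called after subtracting stretch medians. Zinc finger genes named Zfp had a slightly positive median of 0.04 (278 genes, adjusted p 0.0336), with 55 called higher and 23 lower in the authors' deposited table; after subtracting stretch medians the called ones were 7 higher and 20 lower, a turn also seen over all windows (2015 higher and 1060 lower against 456 and 828). Of 40 windows with a gene that fell by at least 2 log2 units, 3 were Zfp genes (Fisher's exact test, odds ratio 2.92, p 0.094).

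Neighbouring promoters shifted together over 7 regions of chromosomes 1, 4, 5, 12 and 16. Chance order was argued against, since 100 shuffles of the changes put at most 29 windows into shifted stretches against 891 in the real order. A trend with accessibility or window width was also argued against, by its small size. Median changes ran from -0.07 in the lowest accessibility decile to 0.10, and were 0.09 in the wider windows and 0.07 in the narrower. All lay within 0.2 log2 of the median of all windows, 0.08. Against outside windows of the same accessibility and width, the smallest regional deviation was 0.21 log2. That matching was no separate test, because it could lower little the deviations for which regions had been chosen (at least 0.2 log2). A candidate explanation is a difference in DNA copy number between the EV and Snai1 populations. The 97 windows of low accessibility that took no part in finding the regions were examined for it. They deviated in their region's direction by a median of 0.43 log2 (95% bootstrap interval 0.33 to 0.54), and 85.6% of them lay on that side. This value was not matched on accessibility and exceeded the median size of their regions' deviation, 0.32. The lowest accessibility decile had a median change of -0.07 over all chromosomes, against 0.08 for all windows. Part of the 0.43 may therefore reflect accessibility where the region was lower. A change of chromatin over whole domains in response to Snai1 would give the same picture and stays open, untested. Reads from genomic DNA of both populations could separate these.

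The endogenous Snai1 window fell by 1.38 log2 in cells that carry extra Snai1. A shift of its neighbourhood was argued against, since the 20 nearest windows had a median change of 0.055 (within 744.5 kb). Cebpb, 150.7 kb away and among those neighbours, rose by 1.90, so the pair moved in opposite directions. Repression of the gene by its own product may explain the lower window, as a hypothesis with no test of its own here, and clonal differences between the populations stay open as well.

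All 10 replication-dependent histone genes with a window, 7 on chromosome 13 and 3 on chromosome 3, were called higher in the authors' deposited table, from 0.33 (H4c9) to 0.53 (H1f2) with a median of 0.42. After subtracting stretch medians the median was 0.24 (p 0.0001, the smallest the random lists can give; adjusted p 0.0048, for a family picked by hand) and 6 stayed called; near-identical copies and overlapping windows make their reads uncertain and the 10 not independent. A regional shift cannot be told apart, because only 12 other windows lay within 200 kb and their deviation from all windows, 0.05, had a bootstrap interval of 0.00 to 0.18 that reaches above 50% of the histone deviation of 0.34. A larger share of Snai1 cells in S phase may be behind it: a list of 41 S-phase genes written before this test, but after the values of 12 members in the cell cycle list had been seen, had a median of 0.075 after subtracting stretch medians (40 genes, random range -0.04 to 0.05, p 0.0022). Of the 40, 12 were called higher and 1 lower in the authors' deposited table, but only 2 were still called higher after subtracting stretch medians. The cell cycle list itself did not pass (adjusted p 0.403). No cell cycle measurement was used here, so this remains a hypothesis.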
